A study of Mus musculus with 2 samples.

How the data were processed

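Total RNA of the nucleoplasmic fraction of mouse bone-marrow-derived macrophages, stimulated with Lipid A at 100 ng/ml for 60 min, was sequenced after depletion of ribosomal RNA, per the labels. The labels give 2 biological replicates of a single condition, from separate biosamples with the same donor label. They also give a fragment size range of 250 to 400, and a starting amount of 1 µg for replicate 1 and 500 ng for replicate 2. Because both libraries share a donor label, the spread between them may be smaller than that between animals.

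Each library came with 3 tables: a gene table, a transcript table of the same layout and a second transcript table of another layout. They were made on the mm10 assembly with the GENCODE M21 annotation, per the file headers. Names of the aligner, the quantifiers and their versions, and the strand setting, are not given in the sources used here. The expected counts in the gene table and in the first transcript table are estimated numbers of reads or fragments that need not be whole and were not normalised, as deposited by the authors. The deposited TPM values are shares of a library after division by effective length, scaled to a fixed sum by the authors. The deposited FPKM values were not used. The estimated counts and the TPM of the second transcript table were deposited by the authors too, and were summed per gene here. Gene TPM differed from the sum of the first table's transcript TPM by at most 0.04. Symbols, gene types and coordinates were taken from GENCODE M21 on the same assembly, to which all 55536 gene entries matched. Coordinates are 1-based.

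The gene tables summed to 21256531 expected counts in replicate 1 and 15643649 in replicate 2, of which 21115765 and 15607391 were on annotated genes. Rows that name no mouse gene were left out of library sizes: the phage phiX174, 96 spike-in controls and 26248 other entries. The phage held 0.662% and 0.232% of the totals. Reads without molecular identifiers are not independent molecules, so intervals and limits of zero counts cover counting error only, with a floor of 3 counts. Genes that overlap, that lie opposite another gene or that have near-identical copies share reads in an unknown way, and their values are uncertain.

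Before the data were examined, 21 gene lists with 372 members were fixed, 5 of them for the response, 9 for other cell types, and the rest for TLR4 signalling, macrophage identity, nuclear-retained RNA, abundant cytoplasmic mRNA, mitochondrial mRNA, cell cycle and replication histones. All members were matched by symbol. A symbol with several gene entries was given the entry with the higher TPM. The level of a list is the median of log2(TPM + 1) of its members in each library, given as mean ± SD over the libraries. It was set against 10000 random lists of the same size from protein-coding genes matched on the decile of effective length. Differences between lists were taken within each library. With 1 group of 2 libraries no test between groups was possible and no p-value is given.

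For the comparison of replicates, expected counts were rounded to whole numbers and normalised by TMM in edgeR 4.0.16 under R 4.3.3, with genes of a mean count of at least 50. Ratios were taken after 0.5 was added to each count. Dispersion was estimated with an intercept alone. Size factors of DESeq2 1.42.0 were an alternative. List medians of the log2 ratio were set against 10000 random lists matched on mean count in 20 bins. For transcript types, members with a TPM of at least 1 in both libraries were used, and the interferon list then includes Mx2, annotated as a polymorphic pseudogene. Other steps used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The replicate comparison was tested on simulated data for 10088 genes, of which 200 were changed. Of those changed by 2 on the log2 scale, 98% were recovered beyond 2-fold, and of those changed by 1.5, 91%, while 0.384% of unchanged genes passed. Of 100 lists of 20 protein-coding genes drawn at random, 1% lay above percentile 95. With 3 added to each value on the log2 scale, 100% did. A shift of that size gives this almost by construction, and smaller shifts were not tried.

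Genes were named by a rule fixed in advance. It took 13 genes in any case, the 5 highest members of each response list, of macrophage identity and of nuclear-retained RNA, and the 3 highest of TLR4 signalling, cell cycle, replication histones and mitochondrial mRNA. It also took the highest member of each list of another cell type, response genes under 3 counts in both libraries, the 10 highest genes, the 5 largest and 5 smallest replicate ratios at a mean count of at least 200, and the gene with the highest retained-intron share in each response list. Cxcl3, Il10, Cxcl9, Nos2, Il12a, Tlr4, Ly96, Pf4, Cd3d, Cd3e, Cd3g, Mir155hg and Xist were added after their values were seen. Alternatives were the pseudocount (0.1), members with a TPM of at least 1, the second transcript table, TPM rescaled over protein-coding genes of the nuclear genome plus the list, CPM without length correction, other normalisations, other count and TPM filters, and leaving out each replicate. One alternative, genes with an annotated retained-intron transcript, was chosen after seeing the data.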

Results

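RNA of the nucleoplasm, the soluble part of the nucleus, was sequenced from mouse bone-marrow-derived macrophages that had received Lipid A at 100 ng/ml for 60 min. Lipid A is the membrane anchor of bacterial lipopolysaccharide and the part that Toll-like receptor 4 (TLR4) recognises. The cells were primary cells of the C57BL/6J strain, and ribosomal RNA was depleted before sequencing, per the labels. The data formed 1 group with 2 biological replicates. Replicate 1 was started from 1 µg of RNA and replicate 2 from 500 ng. The deposited gene tables summed to 21256531 expected counts in replicate 1 and 15643649 in replicate 2. In replicate 1, 11702 genes reached a TPM, a length-corrected share of the library, of at least 1, and 10863 did so in replicate 2. Both libraries shared 10549 of these, of which 8635 were protein-coding, and 15870 genes reached a TPM of 0.1 in both. An unstimulated library, another fraction and another time point were not analysed here. The values below are therefore levels after stimulation, with the spread of 2 libraries, and no gene is described as induced. The SD of a TPM also holds a shift between the libraries. TPM of the median protein-coding gene of the nuclear genome was lower in replicate 2, by a log2 ratio of -0.42. A small SD of TPM is thus no sign that a gene was level between the replicates after normalisation. Where a list is compared with random lists, genes are not independent replicates and the percentile describes these libraries alone.

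The first question was which genes of the macrophage response were present in RNA of the nucleoplasmic fraction at 60 min. Purity of the fraction was not assessed. Transcripts of the mitochondrial genome, which lies outside the nucleus, took 5.64 ± 0.756% of TPM (SD, n = 2). Levels of mRNA may thus include RNA from outside the nucleus. Cytokine and chemokine genes of the early response had the highest median TPM of the 5 response lists. Their list median of log2(TPM + 1) was 7.91 ± 0.25 (SD, n = 2), and 13 of the 20 members had a TPM of at least 100 in both libraries. A list of genes for inhibitors and subunits of the transcription factor NF-κB and of its target genes, here called feedback genes, followed, with a median of 6.84 ± 0.48 (SD, n = 2) over 22 members. The interferon and IRF3 list, which holds the interferon-beta gene and antiviral genes, reached 6.26 ± 0.26 (SD, n = 2) over 26 members. Immediate early genes, which need no new protein for their transcription, had a median of 5.30 ± 0.26 (SD, n = 2) over 26 members. The late inducible list, of genes usually described as later in the response, was the lowest at 3.67 ± 0.30 (SD, n = 2) over 20 members, and 3 of its members had a TPM under 1 in at least one library. The median of each of these 5 lists was above those of all 10000 random lists of protein-coding genes matched on length. The same held for the TLR4, macrophage identity, nuclear-retained, abundant cytoplasmic and mitochondrial lists. Random lists were drawn from genes at any level, and 8635 of the 22028 annotated protein-coding genes had a TPM of at least 1 in both libraries. The comparison thus shows that the lists were expressed in these cells and says nothing of a response.

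**Figure D1:**
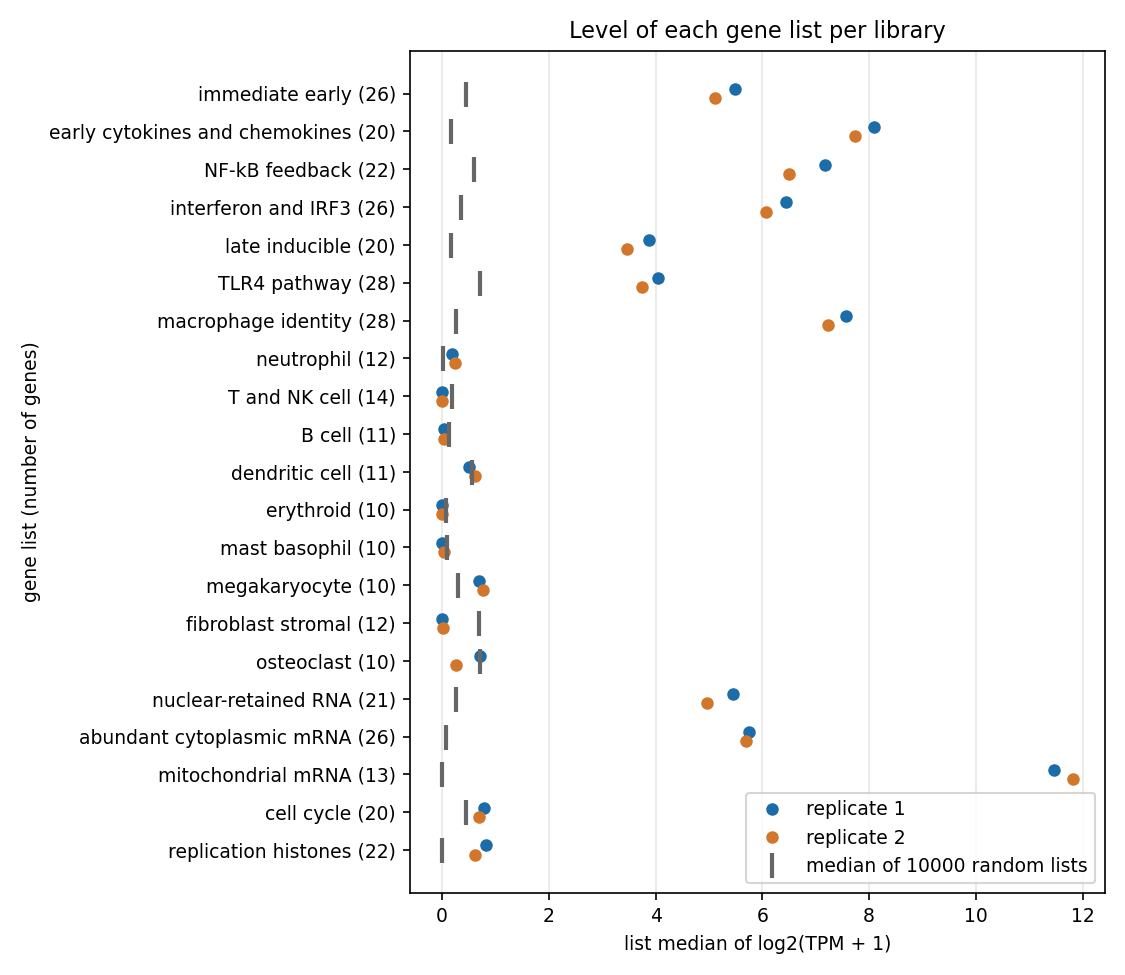
Median of log2(TPM + 1) of each of the 21 gene lists (x axis) in replicate 1 and replicate 2, one point per library, with the number of genes in parentheses and the median of 10000 random length-matched lists of protein-coding genes as a grey bar. The response lists and the macrophage list lie between 3.46 and 8.09, and each list of another cell type lies under 1.

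Tnf, which encodes the cytokine TNF, was the highest member of the cytokine list, at a TPM of 1505 ± 217 (SD, n = 2). It ranked 8 in replicate 1 and 7 in replicate 2 among 22015 protein-coding genes of the nuclear genome. The gene lies on chromosome 17 from 35199381 to 35202007 (mm10). The neutrophil-attracting chemokine gene Cxcl2 followed at 786 ± 174, then the chemokine genes Ccl4 at 727 ± 162 and Ccl3 at 685 ± 75.4, with Il1b, which encodes interleukin-1 beta, at 712 ± 101 (all SD, n = 2). Il10, which encodes an anti-inflammatory cytokine, had a TPM of 84.5 and 126 in replicates 1 and 2. The lowest member was Cxcl3, at 6.59 and 3.87.

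Among the feedback genes, Tnfaip2 was highest at a TPM of 1523 ± 458 (SD, n = 2). Tnfaip3, which encodes the ubiquitin-editing enzyme A20 that restrains NF-κB, stood at 749 ± 129 (SD, n = 2). Nfkbia, which encodes the NF-κB inhibitor IκBα, had 721 in replicate 1 and 377 in replicate 2. Icam1, an adhesion molecule gene, reached 463 ± 172, and Nfkbiz 309 ± 82.1 (both SD, n = 2). All 22 members had a TPM of at least 10 in both libraries, and 10 had at least 100. Nfkbia lies on chromosome 12 from 55489410 to 55492647, and Tnfaip3 on chromosome 10 from 19000910 to 19015657 (mm10).

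In the interferon and IRF3 list the highest member was Rsad2, which encodes the antiviral protein viperin, at a TPM of 646 ± 95.5 (SD, n = 2). The RNA sensor gene Ifih1 stood at 441 ± 16.7, the chemokine gene Ccl5 at 414 ± 93.5, the guanylate-binding protein gene Gbp5 at 277 ± 59.6 and Oasl2 at 261 ± 19.4 (all SD, n = 2). Ifnb1, the interferon-beta gene on chromosome 4 from 88522025 to 88522774 (mm10), had a TPM of 114 ± 7.61 (SD, n = 2), from 1587 expected counts in replicate 1 and 1351 in replicate 2. Cxcl9, a chemokine gene best known as a target of interferon-gamma, was near the limit, with 3 and 5 expected counts.

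Immediate early genes spread over a wide range. Dusp1, a phosphatase gene that ends MAP kinase signalling, had a TPM of 366 ± 80.3 and Gadd45b 296 ± 106 (both SD, n = 2). The transcription factor gene Klf6 stood at 259 ± 61.7, Zfp36, whose protein destabilises cytokine mRNA, at 235 ± 24.0, and the kinase gene Plk2 at 228 ± 88.5 (all SD, n = 2). Fos and Egr1, the best known members, were lower, at 34.5 ± 1.70 and 32.0 ± 6.75 (both SD, n = 2). Fosl1 was the only member of the 5 response lists with fewer than 3 expected counts in both libraries, with 1 and 0. A count of 0 allows up to 3 counts, or 0.192 CPM in replicate 2, for counting error only.

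The late inducible list held both abundant and scarce genes. Clec4e, a receptor for mycobacterial glycolipid, had a TPM of 378 ± 83.1 (SD, n = 2). Acod1, which encodes the enzyme that makes itaconate, stood at 334 ± 134, and the co-stimulatory receptor gene Cd40 at 251 ± 80.4 (both SD, n = 2). The cytokine genes Il12b and Il15 followed, at 69.2 ± 28.8 and 62.4 ± 21.1 (both SD, n = 2). Il6 was at 7.65 ± 0.283 (SD, n = 2). Nos2, the inducible nitric oxide synthase gene, had a TPM of 1.07 in replicate 1 and 0.57 in replicate 2. Il12a had 4 expected counts in replicate 1 and 1 in replicate 2.

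**Figure D2:**
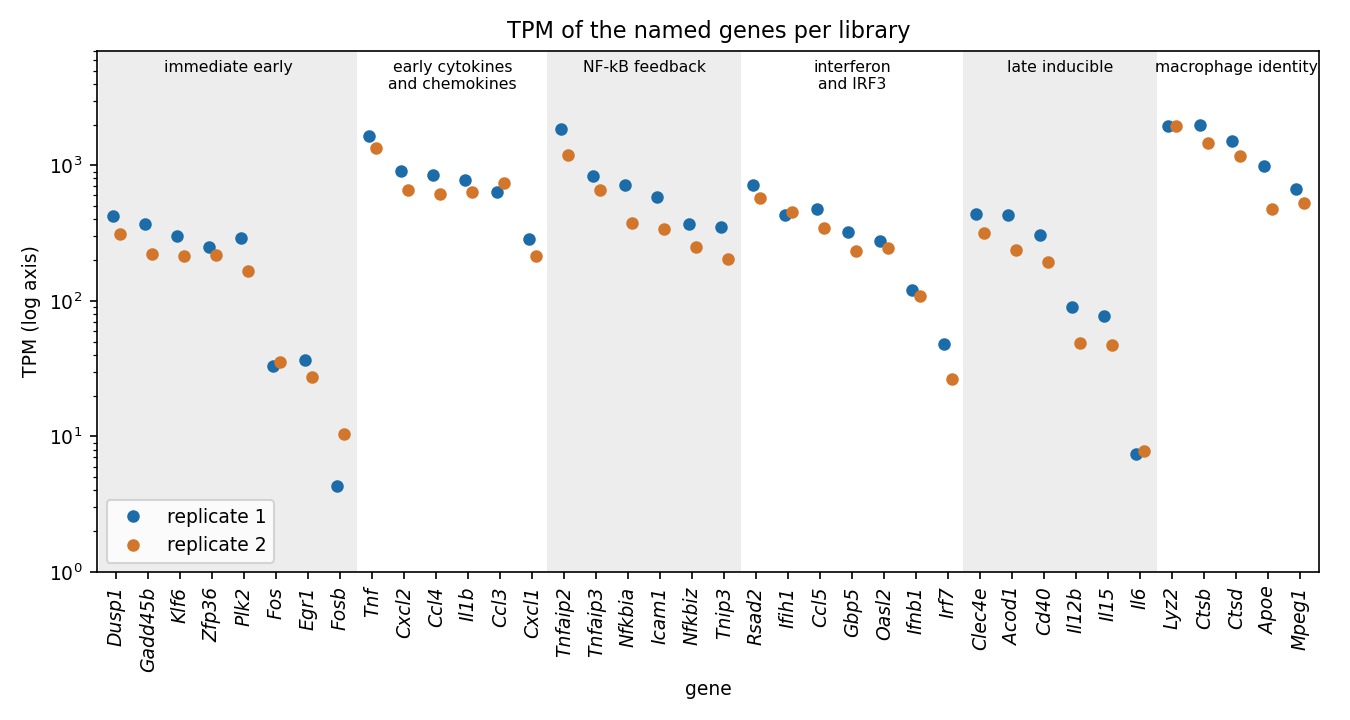
TPM (log axis) of the named genes of the 5 response lists and the macrophage list, with replicate 1 and replicate 2 as one point each and no error bar. Tnf and Tnfaip2 lie above 1000 in both libraries, while Fos, Egr1 and Il6 lie under 100.

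The order of the lists was then compared within each library. Early cytokine and chemokine genes exceeded late inducible genes by 4.24 ± 0.05 (SD, n = 2) on the log2(TPM + 1) scale, and feedback genes exceeded them by 3.16 ± 0.18 (SD, n = 2). Immediate early genes exceeded late inducible genes by 1.63 ± 0.04 (SD, n = 2). Relative to the interferon and IRF3 list, the cytokine list was 1.65 ± 0.01 higher, the feedback list was 0.57 ± 0.22 higher, and the immediate early list differed by -0.96 ± 0.00303 and was thus lower (all SD, n = 2). Each of these 6 differences had the same direction in both libraries and was larger than its SD. With 2 libraries of 1 group no test was made. Without the length correction, in CPM, the cytokine and feedback lists were level, with medians of 8.72 and 8.71. The feedback list then exceeded the interferon list by 1.35, and the immediate early list differed from the late and interferon lists by 2.69 and -0.53. In the second transcript table the feedback list exceeded the interferon list by 1.36, and with members of a TPM of at least 1 alone the immediate early list exceeded the late list by 1.01.

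Components of the TLR4 pathway that receives the Lipid A signal were present at intermediate levels, with a list median of 3.90 ± 0.21 (SD, n = 2), and all 28 members had a TPM of at least 1 in both libraries. Cd14, the co-receptor gene, stood apart at a TPM of 478 ± 24.1 (SD, n = 2). The kinase genes Irak2 and Tbk1 followed at 92.5 ± 20.4 and 70.1 ± 25.6 (both SD, n = 2). Tlr4 itself was at 11.9 ± 2.23 and its partner Ly96 at 13.8 ± 1.72 (both SD, n = 2).

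A further question was whether the libraries carried RNA of other cell types. Macrophage identity genes had a list median of 7.40 ± 0.25 (SD, n = 2), and 26 of the 28 had a TPM of at least 10 in both libraries. Lyz2, the macrophage lysozyme gene, stood at 1939 ± 0.233, the cathepsin genes Ctsb and Ctsd at 1713 ± 372 and 1341 ± 253, the apolipoprotein gene Apoe at 734 ± 362, and the perforin-like gene Mpeg1 at 598 ± 103 (all SD, n = 2). Despite its small SD of TPM, Lyz2 was higher in replicate 2 by a log2 ratio of 0.41 after normalisation of the counts. As a mean over the libraries, every list of another cell type was lower by at least 6.66 on the log2(TPM + 1) scale. The smallest mean difference was that to megakaryocyte genes (6.66 ± 0.30, SD, n = 2), while in replicate 1 that to osteoclast genes was slightly smaller (6.87 against 6.88). The differences to the osteoclast, dendritic cell and neutrophil lists were 6.91 ± 0.07, 6.84 ± 0.32 and 7.18 ± 0.29 (all SD, n = 2). Those to the B cell, T and NK cell, erythroid, mast cell and basophil, and fibroblast and stromal lists were 7.36 ± 0.25, 7.40 ± 0.25, 7.40 ± 0.25, 7.39 ± 0.27 and 7.39 ± 0.26 (all SD, n = 2). The T and NK cell and erythroid medians were 0 in both libraries, and those of the mast cell and fibroblast lists were 0 in replicate 1. The size of all 9 differences depends on the pseudocount, and with 0.1 in place of 1 they lay between 7.81 and 10.71. With members of a TPM of at least 1 alone, the differences were 2.85 to the T and NK cell list, of which Cd4 was then the only member, 3.63 to the megakaryocyte list and 3.73 to the osteoclast list. In the second transcript table, with all members, the 9 differences lay between 5.27 (osteoclast) and 6.27.

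Single members of the lists of other cell types were present, though which cells held their RNA was not tested. In the megakaryocyte list these members were Vwf at a TPM of 37.8 ± 12.4 and Pf4 at 32.5 ± 7.16 (both SD, n = 2). Transcripts not annotated as protein-coding took 51.2% of the TPM of Vwf in replicate 1 and 63.7% in replicate 2. In the osteoclast list, Tnfrsf11a, which encodes the receptor RANK, stood at 25.1 ± 5.54 (SD, n = 2), while Cd4 of the T and NK cell list stood at 22.5 ± 3.02 (SD, n = 2). The T cell receptor complex genes Cd3d, Cd3e and Cd3g had 0 counts in both libraries. The highest members of the other lists were Ccl22 at 3.15 ± 0.544, Cd22 at 1.85 ± 0.488, Mmp8 at 1.81 ± 0.240, Kit at 1.59 ± 0.495, Alas2 at 0.325 ± 0.233 (all TPM, SD, n = 2), and Fn1 at 0.23 in both libraries. Cell-cycle genes had a median of 0.74 ± 0.07 and replication histone genes one of 0.72 ± 0.14 (both SD, n = 2), at percentiles 65.9 and 97.8 of random lists. Mki67 (47.8 ± 12.4), Pcna (36.4 ± 8.41) and Mcm3 (2.64 ± 0.523) were the highest of the former. Hist1h1c (6.67 ± 1.92), Hist1h2bc (3.72 ± 0.990) and Hist1h4c (2.83 ± 1.00) were the highest of the latter (all TPM, SD, n = 2).

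Genes of small structured RNA types took 63.6 ± 6.10% of TPM, a length-corrected unit, but 19.3 ± 9.61% of TPM in the second transcript table and 7.32 ± 2.59% of expected counts. Protein-coding genes of the nuclear genome took 69.9 ± 2.88% of expected counts and Malat1 10.2 ± 0.261% (all SD, n = 2). Of TPM, these protein-coding genes took 22.1 ± 4.71%, and in the second transcript table they took only 13.1 ± 0.918% (both SD, n = 2). The lower share of small structured RNA types there thus did not go with a higher share of protein-coding genes. Which other entries took the remaining TPM there was not examined. The 7SK RNA gene Rn7sk, a regulator of transcription elongation on chromosome 9 from 78175303 to 78175633 (mm10), took a TPM of 189245 in replicate 1 and 278367 in replicate 2, against 51104 and 116638 in the second table. Rpph1, the RNA of ribonuclease P, had 43844 and 107448, and Rmrp, the RNA of the related ribonuclease MRP, had 43429 and 64885 at the first of its 2 overlapping gene entries. At the other entry it had 26792 and 8408, and the division of reads between them is uncertain. Rn7s1 and Rn7s2, near-identical copies of the signal recognition particle RNA gene, were listed at the same value, 52522 ± 1497 each (SD, n = 2). In the second transcript table each of them had 12291 in replicate 1 and 22814 in replicate 2. Rpph1 had 10668 and 42908 there, and the first Rmrp entry 7922 and 25415. Malat1, a long RNA of nuclear speckles, had a TPM of 19450 ± 3041, and Neat1, the scaffold of paraspeckles, 1191 ± 519 (both SD, n = 2). The 10 highest genes, which also included mt-Atp8, mt-Co1 and the small nuclear RNA gene Gm22513, took 47.5% of TPM in replicate 1 and 62.6% in replicate 2. Of these, mt-Atp8 had 8347 and 11846 expected counts and Gm22513 5121 and 2208, so their places rest on the length correction. Because TPM is a share, the median protein-coding gene of the nuclear genome was lower in replicate 2 by a log2 ratio of -0.42 over 8622 genes.

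The nuclear-retained RNA list as a whole took 38.5 ± 11.9% of TPM (SD, n = 2), but its median gene was not above that of abundant cytoplasmic mRNAs. The list median was 5.21 ± 0.34 for the former and 5.72 ± 0.04 for the latter, a difference of -0.51 ± 0.30 (all SD, n = 2). With TPM rescaled over protein-coding genes of the nuclear genome plus the list, the SDs of these 2 medians were 0.51 and 0.26. With members of a TPM of at least 1 alone the difference was -0.11 ± 0.28 (SD, n = 2). Without the length correction of TPM the difference was 1.47, the opposite direction. Actb, the beta-actin gene, had a TPM of 730 ± 119, while the glycolytic gene Gapdh stood at only 49.7 ± 2.24 (both SD, n = 2). The mitochondrial genome took 5.64 ± 0.756% of TPM, ribosomal protein genes 0.281 ± 0.0557% and replication histone genes 0.00276 ± 0.000882% (all SD, n = 2). The mitochondrial mRNA list had a median of 11.64 ± 0.25, with mt-Atp8 at a TPM of 16902 ± 7040, mt-Co1 at 10841 ± 1223 and mt-Nd6 at 5750 ± 1247 (all SD, n = 2). The place of mt-Atp8 rests on the length correction, since it had 8347 and 11846 expected counts against 325600 and 361337 for mt-Co1. In the second transcript table its TPM was 1932 and 5691 in replicates 1 and 2, against 3449 and 5487 for mt-Co1. As shares of expected counts the 10 highest genes took 19.3% and nuclear-retained RNA 17.5%, and in the second transcript table they took 18.7% and 13.8%, the mitochondrial genome 2.75%, ribosomal protein genes 0.127% and histone genes 0.00120%.

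The libraries were next compared with each other. Of 10088 genes with a mean expected count of at least 50, 119 differed by more than 2-fold after normalisation, 51 being higher in replicate 2 and 68 in replicate 1. The median absolute log2 ratio was 0.18, and the common biological coefficient of variation was 0.143. Of genes with a small SD of TPM, Il6 (log2 ratio 0.51), Ifih1 (0.47), Lyz2 (0.41), Gapdh (0.39) and Fos (0.37) exceeded that median. Across genes, Pearson's r of log2 CPM was 0.982 and Spearman's rho of the counts 0.983, for genes that are not independent replicates. With no count filter, 5740 of 22015 genes exceeded 2-fold, and with a mean count of at least 500, 21 of 4061 did.

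Among genes with a mean count of at least 200, those highest in replicate 2 relative to replicate 1 were Fosb (log2 ratio 1.68), Rpph1 (1.60), Mpp7 (1.42), Selenop (1.33) and Gm49369 (1.31), the last of which overlaps Ctsd on the same strand. Fosb encodes an immediate early transcription factor and Selenop a selenium carrier protein. Those highest in replicate 1 were Snord22 (log2 ratio -2.73), the ribosomal RNA entry CT010467.1 (-2.46), the small nuclear RNA gene Gm24265 (-2.16), Gm37376 and Gm26992. Gm37376, which lies opposite Malat1, had 16951 expected counts in replicate 1 and 0 in replicate 2, but in the second transcript table a TPM of 1539 and 2379, the opposite direction. Gm26992 on chromosome X had 609 and 0 expected counts, and a TPM of 44.3 and 3.09 in the second table. Both overlap other genes, so their counts are uncertain.

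As groups, late inducible genes had a median log2 ratio of replicate 2 over replicate 1 of -0.37, with 16 of the 17 tested members higher in replicate 1. Feedback genes had -0.21, with 20 of 22 higher in replicate 1, at percentile 0.21 of random lists matched on expression, and late inducible genes lay below all 10000 of them. Early cytokine and chemokine genes had 0.16, with 14 of 20 higher in replicate 2, at percentile 99.97, but on the scale of log2(TPM + 1), where most tested genes are lower in replicate 2, their median ratio was -0.29. Outside the response lists, mitochondrial mRNAs had 0.43, with 10 of 13 higher in replicate 2, above all 10000 random lists, and abundant cytoplasmic mRNAs 0.11, with 20 of 26 higher, at percentile 99.53. The interferon and IRF3 list (-0.02) and the immediate early list (-0.09) lay at percentiles 63.3 and 12.2. The 65 tested genes of small structured RNA types, which include Rn7sk and Rpph1, had a median of -0.78, and 55 of them were higher in replicate 1, although Rn7sk and Rpph1 were higher in replicate 2. The starting amount of RNA differed between the replicates, and its part in these ratios cannot be separated from the replicate.

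The transcript tables showed how much of each gene's RNA was assigned to transcripts annotated with a retained intron. Feedback genes had a mean share of 27.9 ± 0.290% and interferon and IRF3 genes one of 25.9 ± 0.864% (both SD, n = 2). The share was 11.0 ± 1.08% in immediate early genes, 8.69 ± 0.439% in early cytokine and chemokine genes, 8.63 ± 0.390% in late inducible genes and 3.77 ± 0.455% in macrophage identity genes (all SD, n = 2). TLR4 pathway genes had 23.8 ± 1.48% and abundant cytoplasmic mRNAs 19.4 ± 1.15% (both SD, n = 2). Over all 8622 protein-coding genes with a TPM of at least 1 in both libraries the mean was 19.6 ± 0.0253% (SD, n = 2). All transcripts not annotated as protein-coding together took 34.9 ± 0.593% in feedback genes, 37.4 ± 0.663% in interferon and IRF3 genes, 12.8 ± 1.33% in immediate early genes, 12.4 ± 1.11% in the cytokine list and 13.6 ± 0.250% in the late list (all SD, n = 2). Many genes have no annotated retained-intron transcript and then count as 0. Among genes that have one, the means were 36.1% for feedback genes, 38.2% for interferon and IRF3 genes, 29.4% for immediate early genes, 21.7% for the cytokine list, 48.9% for the 3 late genes, 10.5% for macrophage genes, 31.7% for TLR4 pathway genes and 21.9% for abundant cytoplasmic mRNAs. All 5609 such protein-coding genes had a mean of 30.1%, close to that of immediate early genes.

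The highest share within each of the 5 response lists was found in Tnip3 (86.6 ± 1.16%), an inhibitor of NF-κB signalling, in Clec4e (68.1 ± 4.34%), in Dusp1 (67.5 ± 3.44%), in the interferon regulatory factor gene Irf7 (64.7 ± 0.927%) and in Cxcl1 (34.4 ± 2.68%) (all SD, n = 2). These were not the highest of all genes, since Lilrb4a outside the lists had 96.4%, and Ccl5 of the interferon list, at 63.9%, exceeded Cxcl1. Tnip3 lies on chromosome 6 from 65525313 to 65634040 and Dusp1 on chromosome 17 from 26505590 to 26562128 (mm10).

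**Figure D3:**
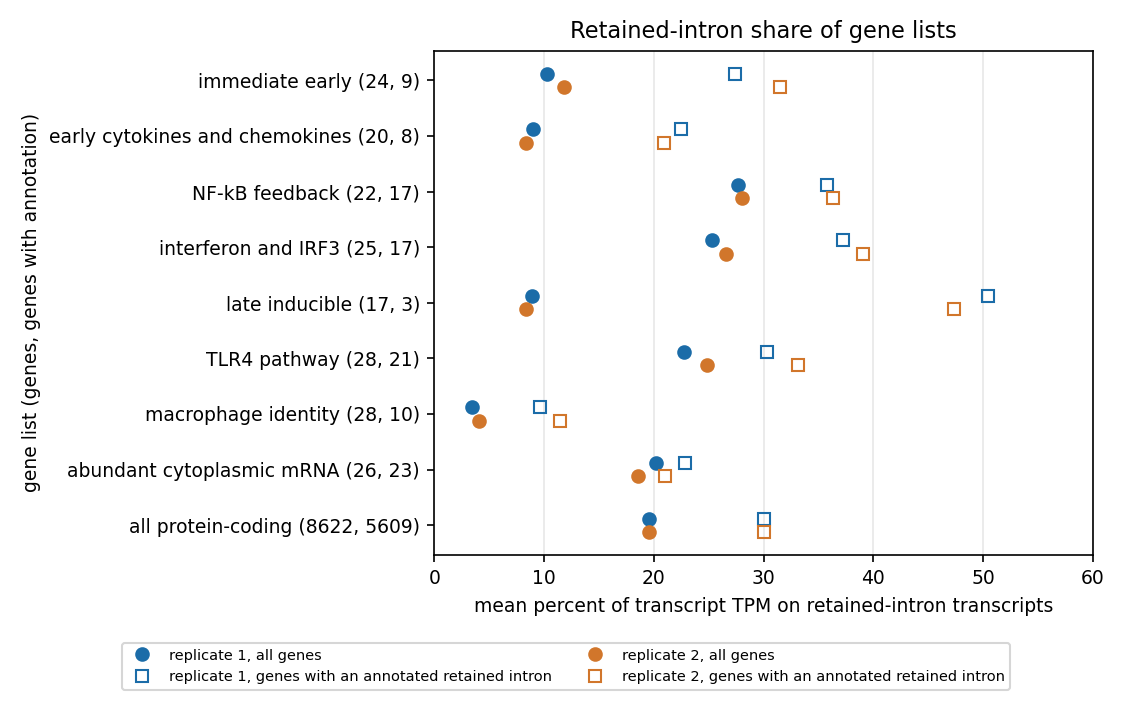
Mean percent of transcript TPM on transcripts annotated with a retained intron (x axis) for each gene list and for all protein-coding genes, in replicate 1 and replicate 2. Filled circles are all genes with a TPM of at least 1 in both libraries, open squares those with an annotated retained-intron transcript, and the numbers of both are in parentheses. Macrophage identity genes have the lowest mean on either scale, 3.77% and 10.5%.

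Each library had been quantified by another method as well, in a second transcript table. Summed per gene, its TPM had a Pearson's r of 0.925 with the gene table on the log2 scale over 9941 genes in replicate 1, and of 0.920 over 9838 genes in replicate 2, with genes as the units. After centring, 1157 genes in replicate 1 and 1043 in replicate 2 differed by more than 2-fold. The second table gave lower TPM for the typical gene, by a median log2 difference of -1.02 in replicate 1 and -0.48 in replicate 2.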

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

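All tests in this part were chosen after the rows were seen, and they are given as values alone. Signal was present in entries that name no mouse gene. The phage phiX174, often added to sequencing runs as a control, had 140756 expected counts in replicate 1 (0.662%, exact 95% binomial interval 0.659 to 0.666) and 36247 in replicate 2 (0.232%, interval 0.229 to 0.234). The gene tables listed 0 counts for all 96 spike-in control entries. The second transcript table listed 22 counts for the control ERCC-00099 in replicate 2 and 2 in replicate 1, against a limit of 3 counts for a count of 0. No explanation was tested.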

How the results depend on the processing

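No paired analysis was possible because the data hold a single group. Leaving out either replicate moved no result by more than 1 SD, which 2 values cannot do by construction, so this says nothing about stability. Of the 16 differences between lists, 15 kept their direction under every alternative tried. The exception was nuclear-retained RNA minus abundant cytoplasmic mRNA, which turned to 1.47 in CPM (counts scaled to library size) without length correction. The cause was not tested, but that setting leaves out transcript length. Erythroid and fibroblast genes had no member with a TPM of at least 1 in both libraries, so they gave no value under that filter. DESeq2 size factors moved none of the 7 replicate results run with them. Library totals alone were run only for the genes beyond 2-fold between replicates, which numbered 124 against 119. Each value below moved by more than 1 SD (2 libraries), or by more than 1.5 times for counts, and beyond what is said of construction the cause was not tested. Lists are given in the order immediate early, cytokine, feedback, interferon, late, macrophage, nuclear-retained and cytoplasmic. Other cell types follow the order neutrophil, T and NK, B, dendritic, erythroid, mast, megakaryocyte, fibroblast and osteoclast.

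With the second transcript table, list medians were 4.39, 7.33, 5.11 (interferon), 2.98, 6.30, 4.42 and 4.75, with feedback within 1 SD. Differences from the late list were 1.41, 4.35 and 3.50, and from the interferon list -0.73, 2.21 and 1.36. Macrophage genes exceeded the other cell types by 5.92, 6.19, 6.21, 5.85, 6.27, 6.27, 5.74, 6.16 and 5.27. Shares of TPM were 2.75% for the mitochondrial genome, 0.127% for ribosomal protein genes, 13.8% for nuclear-retained RNA, 18.7% for the 10 highest genes and 0.00120% for histones. Retained-intron shares were 12.6% (immediate early), 9.72% (cytokine), 28.5% (feedback) and 4.69% (macrophage). TPM rescaled over protein-coding genes, which raises every level by construction, gave medians of 7.47, 10.10, 9.02, 8.44, 5.77, 9.59, 5.92 and 7.89. Their SDs were 0.04, 0.06, 0.17, 0.05, 0.01, 0.06, 0.51 and 0.26. The ranking of lists by spread between the libraries thus depends on the scaling. Differences were then 1.70 and 4.33 from the late list for immediate early and cytokine genes, and -0.97 from the interferon list for immediate early genes. Macrophage genes exceeded the other cell types by 8.80, 9.59, 9.40, 7.92, 9.59, 9.52, 7.58, 9.53 and 8.17, and nuclear-retained minus cytoplasmic RNA was -1.97.

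In CPM, medians were 6.83, 8.72, 8.71, 7.36, 4.15, 7.94, 7.51 and 6.04. Differences from the late list were 2.69, 4.57 and 4.56, and from the interferon list -0.53, 1.36 and 1.35. Macrophage genes exceeded neutrophil, T and NK, B, erythroid, mast, fibroblast and osteoclast genes by 7.79, 7.94, 7.82, 7.94, 7.92, 7.89 and 7.09. With members of a TPM of at least 1 alone, medians were 4.41 (late) and 5.61 (nuclear-retained). Differences were 1.01, 3.50 and 2.43 from the late list, and -0.90 and 1.59 from the interferon list for immediate early and cytokine genes. Macrophage genes exceeded neutrophil, T and NK, B, dendritic, mast, megakaryocyte and osteoclast genes by 5.94, 2.85, 5.90, 5.36, 6.04, 3.63 and 3.73, and nuclear-retained minus cytoplasmic RNA was -0.11. With a pseudocount of 0.1, immediate early and cytokine genes exceeded the late list by 1.71 and 4.35, and immediate early genes differed from the interferon list by -0.98. Macrophage genes exceeded the other cell types by 9.39, 10.71, 10.34, 8.20, 10.71, 10.59, 7.81, 10.61 and 8.50.

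Genes beyond 2-fold between replicates numbered 5740 with no count filter and 21 with a mean count of at least 500, settings that change which genes are counted. On the log2 scale of TPM + 1, replicate ratios were -0.49, -0.61, -0.42 and -0.62 for immediate early, feedback, interferon and late genes, and for cytokine genes -0.29, the opposite direction. The median of all 10088 genes tested was -0.35 on that scale. As shares of expected counts, ribosomal protein genes took 0.192%, nuclear-retained RNA 17.5% and the 10 highest genes 19.3%. At a TPM of at least 0.1, 15870 genes were detected in both libraries. At a TPM of at least 5, retained-intron shares were 8.84%, 7.65%, 24.4% and 7.47% in immediate early, cytokine, interferon and late genes. Among genes with an annotated retained-intron transcript, chosen after seeing the data, they were 29.4%, 21.7%, 36.1%, 38.2%, 48.9% and 10.5% from immediate early to macrophage genes. Pearson's r between the quantifications was 0.918 at a TPM of at least 10.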

Other observations

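Genes outside the fixed lists also reached high levels, and those named here were chosen after their values were seen. The highest protein-coding genes of the nuclear genome outside the lists were Psap, which encodes the lysosomal activator prosaposin, at a TPM of 4468 and 3008 in replicates 1 and 2, the receptor gene Lilr4b at 3193 and 2644, Gpnmb, which encodes a lysosomal and membrane glycoprotein, at 2724 and 2000, and Lilrb4a at 2429 and 2070. Transcripts not annotated as protein-coding took 95.7% and 95.1% of the TPM of Lilr4b and 100% of that of Lilrb4a in both libraries. The MHC class I genes H2-K1 and H2-D1 followed, at 1604 and 1178 and at 1458 and 930, then the osteopontin gene Spp1 at 1021 and 652. Malt1, whose product is a signalling protease upstream of NF-κB, stood at 821 and 603, and the inflammasome sensor gene Nlrp3 at 515 and 277. Of the 50 highest protein-coding genes of the nuclear genome in each library, 43 were shared. Of these, 11 belonged to a response list and 6 to macrophage identity.

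Genes of long noncoding types took 4.95 ± 2.03% of TPM and 14.4 ± 1.06% of expected counts (both SD, n = 2), 10.2% of the counts being Malat1. The class also holds the Rmrp entry annotated as lincRNA, with a TPM of 26792 and 8408 in replicates 1 and 2, against 21601 and 17300 for Malat1. Among members of the nuclear-retained list, also chosen after their values were seen, Mir155hg, the host transcript of the microRNA miR-155, had a TPM of 376 ± 73.9, and Xist 325 ± 133 (both SD, n = 2). Outside the lists, Gm26917 had 2005 and 535, Gm42418, which overlaps the ribosomal RNA entry CT010467.1, 1245 and 666, Lncpint 347 and 243, the host transcript Mir22hg 297 and 171, and Gm14636 on chromosome X 832 and 586. Gm26917 lies on chromosome 17 from 39843013 to 39846341, directly beside CT010467.1 at 39846353 to 39848827 (mm10). Whether Gm26917 and Gm42418 hold reads of ribosomal RNA was not tested. Gm40578, annotated antisense and overlapping Tnfaip2, had 140 and 118, and Gm14023, which overlaps Il1a, had 93.1 and 86.1. Their reads cannot be separated from those of the overlapping genes without a known strand setting.

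In the following patterns, the tests of missing annotation and read assignment for retained introns were chosen only after the result was seen. Mki67, a proliferation marker, had a mean TPM of 47.8, which was 79.7 times the median of the other 19 cell-cycle genes in replicate 1 and 66.3 times in replicate 2. That median lay under 1, and Mki67 did not stand alone, since Pcna of the same list had 42.3 and 30.4 against 56.6 and 39.1 for Mki67. Against shared reads, 0 annotated genes overlap an exon of Mki67, and against the way reads were assigned to transcripts, the second transcript table kept a ratio of at least 36.8 in both libraries. Dividing cells stay open as a source, since a comparison with the other 19 members was run but restates the pattern, and it was set aside. No biological explanation was tested, since the design holds no other condition.

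Feedback genes had a retained-intron share 24.1 percentage points above that of macrophage genes. Missing annotation would not account for this as a whole, since among genes with an annotated retained-intron transcript the difference was at least 24.9 percentage points in both libraries. In the second transcript table the difference was at least 23.7, so it did not arise from 1 method of assigning reads alone. Both methods used the same annotation, so intronic reads of unspliced RNA could go to retained-intron transcripts in both, and this test cannot exclude that. Expression level was argued against for the macrophage genes, whose mean lay at percentile 0 of random lists matched on TPM. Feedback genes lay at percentile 63.5 of such lists, so the pattern may be one of a low share in macrophage genes rather than of a high share in feedback genes. A low share was not particular to macrophage genes, since abundant cytoplasmic mRNAs lay at percentile 0.28 and cytokine genes at 4.71. No biological explanation was tested.

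Genes of the types TEC and sense-intronic that lie within an intron of a protein-coding gene followed their host. Of 410 such genes on the strand of a host with a TPM of at least 10, 89.0% had at least 10 counts in both libraries, and of 795 within a host under 1, 2.39% did, a ratio of 37.2 that argues against transcription independent of the host for the set as a whole. Across the 1670 same-strand genes, which are not independent replicates, Spearman's rho with the host's TPM was at least 0.841 in both libraries, as unspliced RNA of the host would give, with Gm38357 in Noct (309 and 199, host 395 and 264) and Gm43430 in Nfkb1 (71.7 and 53.7, host 267 and 198) as examples chosen after their values were seen. Some same-strand genes were above their host in both libraries, among them Gm47087 in Maml2 (44.8 and 44.6, host 4.06 and 3.23) and Gm43982 in Etv6 (38.2 and 24.8, host 16.2 and 10.1), and for these a source other than the host stays open. The 223 genes on the opposite strand had 0.812 in replicate 1 and 0.794 in replicate 2, a gap below the 0.1 set before the result was seen. Of the 47 in a host with a TPM of at least 10, 83.0% had at least 10 counts in both libraries. Of the 114 in a host under 1, 4.39% did, so that split was not particular to the strand of the host. Unspliced host RNA counted without regard to strand, and shared activity of the locus, cannot be told apart by these values.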
